A study of Homo sapiens with 8 samples.

How the data were processed

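Chromatin immunoprecipitation with sequencing was used to map SOX2, OCT4 and NANOG in 2 human pluripotent lines. H9 is an embryonic stem cell line and NT2/D1 is an embryonal carcinoma line. The labels name 8 samples: 3 factors and an IgG control in each line. The 6 factor libraries were analysed through their peak lists, and the 2 IgG samples were not analysed here on their own. Each factor and line had 1 library, so there were no replicates.

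Peaks were called with MACS for each library on its own against an IgG library, without pooling, per the file headers; the MACS version and the aligner were not given in the sources used here. The genome build was hg19, per the submitters' processing notes. Reads came from SOLiD sequencing with a tag size of 50, and the p-value cutoff was 0.001, per the file headers. The settings were not alike in the 2 lines. The band width was 2000 in H9 and 200 in NT2/D1, and the model fold was 3 except for NT2/D1 OCT4, where it was 5, per the file headers. The 3 H9 lists were called against the same IgG library. In NT2/D1 the SOX2 and NANOG lists shared an IgG library and the OCT4 list had another, per the file headers; which of them is the IgG sample in the labels was not worked out.

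The deposited tag count of a peak is the whole number of ChIP tags in it, not normalized. The deposited fold enrichment is the authors' ratio over background. The deposited FDR is in percent, per the file headers. The name of the deposited score column had been overwritten, and the score was read as the negative log10 of the p-value multiplied by 10, because its lowest value was 30 in every list and the stated cutoff was 0.001. The nearest gene on each side and its distance had been added to the deposited lists by the submitters, per the file headers. Tag counts, folds and scores are the authors' own values and were used only to describe, rank or filter peaks within a list.

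The unique tags per library were 72186968 for H9 SOX2, 77649240 for H9 OCT4, 54046559 for H9 NANOG, 23160564 for NT2/D1 SOX2, 10218752 for NT2/D1 OCT4 and 19669139 for NT2/D1 NANOG, per the file headers. The IgG library behind the NT2/D1 SOX2 and NANOG lists had 2937004 unique tags of 17173085 (17.1%). The other NT2/D1 IgG library had 6479071 of 12359411 (52.4%), and that of H9 had 58012070 of 84245266 (68.9%). A threshold of 5% FDR has a different meaning in these lists. Across the peaks of a list, FDR fell with score in H9 and in NT2/D1 OCT4 (Spearman rho of -0.980, -0.950, -0.890 and -0.991) but rose with it in NT2/D1 SOX2 and NANOG (rho of 1.00 in each), where the FDR limit removes the strongest peaks.

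Libraries were assigned to groups by their titles. For NT2/D1 the source names of the OCT4 and NANOG libraries are exchanged relative to title and description, and the exchanged reading was run as an alternative. Peaks of different lists were merged where they overlapped by at least 1 bp, and a region counted for a factor where it held a peak of that list. Overlaps were set beside 100 random placements of every peak on its own chromosome, uniformly or, as an alternative, shifted by 20 to 200 kb. The placements describe these lists and give no p-value. Shares carry 95% Wilson intervals, which cover counting error only. No test between libraries was possible.

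A peak was assigned to the nearer of the 2 genes the authors list, within 50 kb of the transcription start site (TSS). Symbols came from RefSeq accessions, of which 23834 of 25013 (95.3%) matched the RefSeq table of a later assembly, used for names only. This also restored 556 gene fields that held a date in place of a symbol. TSS positions of 18204 genes were recovered from the distances, where at least 2 votes pointed to the same position. The share of each of 15 gene lists with a peak was set beside 10000 random lists of the same size, matched on deciles of the span in which a peak would be assigned to the gene. The percentile is a description of these libraries. The lists, the alternatives and the rule for named genes were fixed before the data were examined. CGB, DND1, DNMT1, CCNB1, CDK2, CDK4, APOA2, FGA, CD3G, CD79A, CD14, NKG7 and S100A4 had no recovered TSS and did not enter the lists.

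The genes named are the members of the core pluripotency list; the genes nearest to the 15 regions with all 3 factors in both lines whose lowest within-list score percentile was highest; those of 10 such regions called only in H9 and of 10 called only in NT2/D1; those of the 5 peaks with the highest score in each list; and up to 4 members of each other list with the highest percentile in any library. A few genes that this rule names are not reported here. After the data were seen, the regions called only in NT2/D1 were limited to chromosomes 1 to 22 and X.

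The alternatives were the upper 50% of each list by score, lists of equal length (19349 peaks), summits within 200 bp, a reciprocal overlap of 50%, local random placement, lists without the widest 1% of peaks and without chromosomes other than 1 to 22 and X, the exchanged NT2/D1 libraries, an FDR of at most 5%, a fold of at least 10, gene assignment within 5 kb and promoters of 5 kb in place of 1 kb. Lists without chromosomes 1, 2, 3, 7, 9 and 12, which were picked without a rule, and gene lists with the NT2/D1 libraries exchanged, were added after seeing the data. Motif searches need a genome sequence of the build and were not run.

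The overlap and gene-list code was tested on simulated data. Over lists of 10000 simulated peaks, recovered overlaps lay within 1% of the planted ones. With 18204 genes, 1.5% of 200 unchanged lists and 100% of 50 planted lists of 25 genes passed the 95th percentile. Simulated genes with a peak were drawn singly and without regard to span, so binding that follows span and clustered genes were not tried. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.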

Results

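SOX2, OCT4 and NANOG, transcription factors that maintain the pluripotent state, were mapped by ChIP-seq in the human embryonic stem cell line H9 and in NT2/D1, an embryonal carcinoma line. The 6 peak lists held 201619 peaks. There were 19349 for SOX2, 29575 for OCT4 and 33895 for NANOG in H9, and 38423, 46169 and 34208 in NT2/D1. The H9 libraries had 54046559 to 77649240 unique tags and those of NT2/D1 10218752 to 23160564, and the median peak held 46, 32 and 40 tags in H9 but 11, 7 and 9 tags in NT2/D1. Each factor and line had 1 library, so no difference between libraries could be set against a replicate error. Intervals cover counting error only, and tag counts, folds and scores of peaks are the authors' values.

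Some of the strongest peaks lay at the same loci in several lists. In H9 the 5 peaks with the highest score were nearest to PRDM14, ANKRD1, FBRS, MIR9-2HG and KCNJ2 for SOX2. For OCT4 they included peaks nearest to FBRS, MAP3K7, MIR9-2HG and ANKRD1, and for NANOG they were nearest to AUTS2, PCDH11X, MIR9-2HG, MAP3K7 and MARCKS. The last 3 of the NANOG peaks had the same score. In NT2/D1 the strongest SOX2 peaks were nearest to DNAJB6, ETV6, ITPRID1, SPATA45 and PJA1, and the strongest NANOG peaks to MYO1E, NPY, ITPRID1, PRDM14 and DNAJB6. The NT2/D1 OCT4 list was led by a peak on mitochondrial DNA with 948 tags and a fold of 5.42, followed by KDM4A, ETV6, SMAD7 and ING2. The region 93.3 kb from PRDM14, a regulator of pluripotency, reached a fold of 38.6 for SOX2 in H9 (chromosome 8, 70889299 to 70890285) and 54.3 for NANOG in NT2/D1.

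Most peaks lay away from gene starts, and by the titles OCT4 had the highest promoter share in both lines. Within 1 kb of a TSS lay 10.5% of the OCT4 peaks in H9 (95% interval 10.1 to 10.8) and 12.03% in NT2/D1 (11.7 to 12.3). For NANOG the shares were 7.65% (7.37 to 7.93) and 4.44% (4.22 to 4.66), and for SOX2 4.38% (4.10 to 4.68) and 3.44% (3.26 to 3.62). With the NT2/D1 libraries exchanged, the NT2/D1 share would be 4.44% for OCT4 and 12.03% for NANOG, so the order there rests on the titles. The NT2/D1 list titled OCT4 also had another IgG library and model fold than the other NT2/D1 lists. The median distance to the nearest TSS was 43.7 kb for H9 OCT4, 58.9 kb for H9 NANOG and 74.9 kb for H9 SOX2, and 40.9, 46.2 and 54.6 kb for the same factors in NT2/D1.

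The 3 factors met at many sites in H9. Of 55578 merged regions, 8195 held peaks of all 3 factors (14.7%, 95% interval 14.5 to 15.04), against a mean of 6.58 in random placements and 20.9 with local placement. Regions with all 3 factors took in 43.0% of SOX2 peaks, 29.3% of OCT4 peaks and 24.5% of NANOG peaks. At POU5F1, which encodes OCT4, all 3 factors lay 932 to 1091 bp from the TSS, with 429 tags for SOX2 (fold 24.3), 296 for OCT4 (fold 10.7) and 571 for NANOG (fold 38.2). At SOX2, the strongest H9 peaks of all 3 factors lay 43.8 to 43.9 kb from the TSS, with folds of 19.0, 15.6 and 13.7. At NANOG, SOX2 and OCT4 peaks overlapped the TSS, with folds of 12.9 and 7.53, and the strongest NANOG peak lay 8205 bp away with a fold of 8.69. The 3 H9 lists were called against the same IgG library, so part of the excess over random placement may come from the shared control.

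In NT2/D1, 1910 of 106926 regions held all 3 factors (1.79%, 95% interval 1.71 to 1.87), against a mean of 12.5 in random placements and 30.2 with local placement. The SOX2 and NANOG lists shared an IgG library with 2937004 unique tags, so part of this excess may also come from the shared control. Peaks of a single factor made up 91.0% of the NT2/D1 regions and 67.3% of the H9 regions. These shares count every called peak, and false calls among them were not separated in either line. In NT2/D1 an FDR of at most 5% was met by 22.5% of OCT4 peaks, 83.0% of SOX2 peaks and 76.3% of NANOG peaks. For SOX2 and NANOG the FDR rose with score, so this limit does not mark their weak calls. The shares therefore do not show how often a factor bound alone. POU5F1 had peaks of all 3 factors in NT2/D1, with 43 tags for SOX2 (fold 19.2), 57 for OCT4 (fold 19.7) and 62 for NANOG (fold 55.3). Near SOX2, SOX2 and OCT4 peaks lay 3943 and 3986 bp from the TSS, with folds of 18.9 and 25.8, and no NANOG peak was assigned to the gene within 50 kb. At NANOG, an OCT4 peak overlapped the TSS with 23 tags and a fold of 13.2, and no SOX2 or NANOG peak was assigned to the gene. With fewer tags and other calling settings in NT2/D1, a peak that was not called is not shown to be absent.

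For each factor, a minority of H9 peaks was called in NT2/D1, and the strongest H9 peaks were called most often. OCT4 had the highest share. The NT2/D1 OCT4 list overlapped each H9 list most, with 32.1% of H9 SOX2 peaks and 23.8% of H9 NANOG peaks, so the first place of OCT4 is not particular to H9 OCT4 peaks. Of H9 OCT4 peaks, 26.1% overlapped an NT2/D1 OCT4 peak (95% interval 25.6 to 26.6), against a mean of 1.24% in random placements. For SOX2 the share was 16.2% (15.7 to 16.7) against 1.497%, and for NANOG 9.83% (9.52 to 10.1) against 1.34%. In the highest decile of each H9 list by score, 71.1% of OCT4 peaks, 55.0% of SOX2 peaks and 42.5% of NANOG peaks were shared. In the lowest decile the shares were 9.91%, 4.55% and 3.04%. With the NT2/D1 OCT4 and NANOG libraries exchanged, as their source names have them, the share was 8.33% for OCT4 and 23.8% for NANOG, so the order of these factors rests on the titles.

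**Figure D1:**
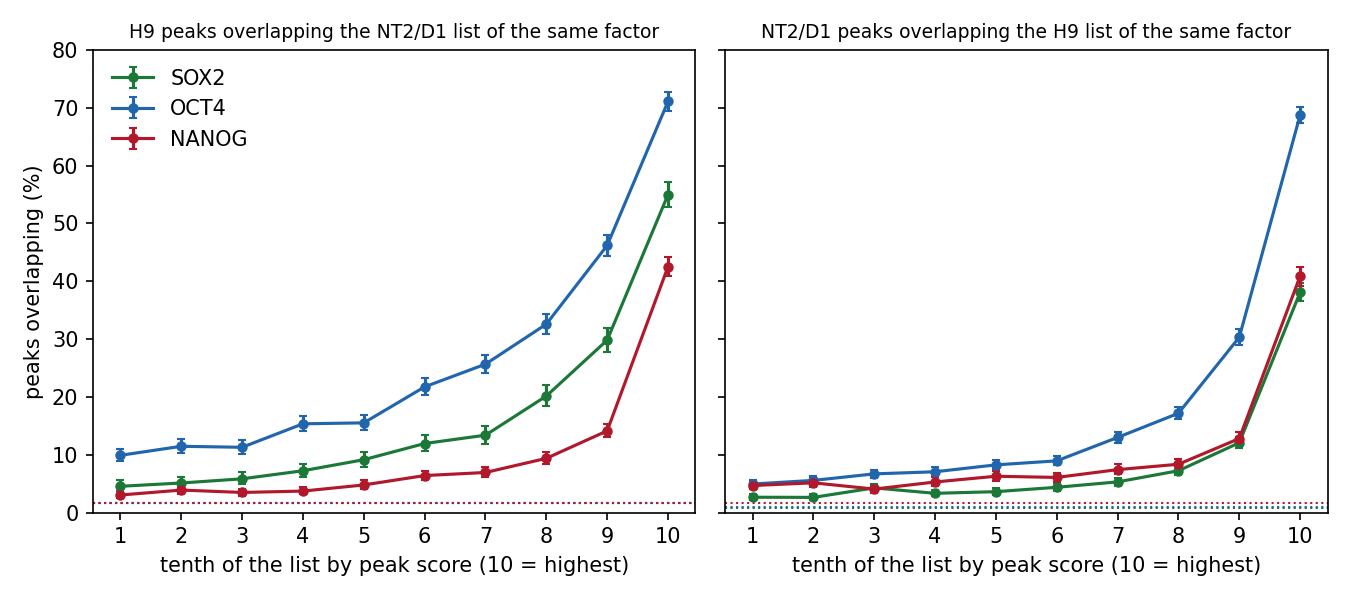
Share of peaks (%, vertical axis) that overlap the list of the same factor in the other line, by decile of the list by score (horizontal axis), for H9 peaks (left) and NT2/D1 peaks (right). Bars are 95% Wilson intervals and dotted lines the mean of 100 local random placements; the highest decile of H9 OCT4 peaks reached 71.1% and the lowest 9.91%.

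Peaks of all 6 lists met in 1218 regions, against a mean of 0.06 in random placements. The region with the highest lowest percentile lay 8035 bp from the TSS of MIR9-2HG, the host transcript of a microRNA gene (chromosome 5, 87959052 to 87961346), with folds of 41.5, 25.2 and 51.5 for SOX2, OCT4 and NANOG in H9 and 31.1, 20.6 and 33.5 in NT2/D1. It was followed by regions nearest to PPP1R3B, SLC25A13, ETV6 and CNTN5. The ETV6 region (chromosome 12, 11761641 to 11762934), 40.3 kb from the TSS, had folds of 30.5, 21.5 and 42.6 in H9 and 40.8, 23.8 and 31.7 in NT2/D1. The other 10 of the 15 highest regions were nearest to FBRS, SHB, NKX6-1, ITPRID1, UBE2D2, DPPA5, RCC2, TMEM132D, FAT4 and KCNJ2. DPPA5, an early embryonic and germ cell gene, lay 4201 bp from its region, while the region assigned to CNTN5 lay 1163531 bp from its TSS.

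Regions with all 3 factors in NT2/D1 were mostly H9 sites. When regions were merged over all 6 lists, which joins neighbours, 1959 regions held all 3 factors in NT2/D1 and 8196 in H9. Of the NT2/D1 regions, 62.2% (95% interval 60.0 to 64.3) held all 3 factors in H9 and 83.0% (81.2 to 84.6) held at least 1 H9 peak. Of the H9 regions, 14.9% (14.1 to 15.6) held all 3 factors in NT2/D1 and 59.4% (58.3 to 60.4) held at least 1 NT2/D1 peak. The NT2/D1 OCT4 list recovered 53.0% of the H9 regions, the SOX2 list 27.8% and the NANOG list 22.3%.

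No NT2/D1 peak was called in 3331 H9 regions with all 3 factors. The 10 highest by percentile were nearest to PHF21B, ADAM29, OSTF1, CHAC2, SLITRK1, ATXN8OS, LOC392145, OLFM4, TENM4 and ZNF717. The first, 21.5 kb from the TSS of PHF21B (chromosome 22, 45427144 to 45428544), had folds of 16.5, 12.1 and 21.4 for SOX2, OCT4 and NANOG. On chromosomes 1 to 22 and X, no H9 peak was called in 332 NT2/D1 regions with all 3 factors, of which the highest included those nearest to KIF15, RPA4, SOX21, FOXI3, FBXL14, HECW1, LMNTD1 and FERRY3. A region 236 kb from SOX21, a neural SOX factor, had folds of 9.62, 13.7 and 9.86 (chromosome 13, 95600088 to 95600722). SOX21 itself also had a region with all 3 factors within 50 kb in both lines. An H9 OCT4 peak lay 4982 bp from its TSS with a fold of 10.7. The regions at FBXL14 and FERRY3, each within 1 kb of a TSS, held peaks of 1 list after the widest 1% of peaks and chromosomes other than 1 to 22 and X were left out.

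The core pluripotency genes carried peaks in both lines. In H9, 23 of 32 had a region with all 3 factors within 50 kb, against a mean of 5.60 in random lists (percentile 100). In NT2/D1, 16 of 32 had one, against 1.74 (percentile 100), and 7 had one within 5 kb. DPPA4, FOXD3, GDF3, JARID2, L1TD1, LEFTY1, LIN28B, PODXL, POU5F1, SALL4, TCF7L1, TERF1, TRIM71, UTF1 and ZFP42 had such a region in both lines. CRIPTO, DNMT3B, LEFTY2, MYC, NANOG, NODAL, SOX2 and ZSCAN10 had one in H9, and LIN28A in NT2/D1. CDH1, DPPA2, ESRRB, FGF4, KLF4, MYCN and PRDM14 were among those with none within 50 kb in either line. TERF1, a telomere-binding factor gene, had folds of 24.1, 12.9 and 38.0 for SOX2, OCT4 and NANOG in H9 and 31.2, 25.2 and 24.6 in NT2/D1. The SOX2 peak 997 bp from a TSS of DNMT3B, a DNA methyltransferase gene, had 48 tags and a fold of 39.6 in NT2/D1. SALL4 had its strongest NT2/D1 peak for NANOG, with 52 tags and a fold of 41.4.

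Signalling genes were also near regions with all 3 factors. These lists are not separate from the core pluripotency list. LEFTY1, LEFTY2, NODAL and CRIPTO are also in the Nodal, TGF-beta and BMP list, and TCF7L1 is also in the WNT list. In H9 these were 15 of 26 genes of the Nodal, TGF-beta and BMP list (random mean 4.52, percentile 100), 12 of 19 of the FGF and ERK list (4.60, percentile 100) and 18 of 26 of the WNT list (5.52, percentile 100). In NT2/D1 they were 7 (1.41, percentile 100), 5 (1.32, percentile 99.6) and 5 (1.70, percentile 98.5). Within 5 kb they were 1 (percentile 79.9), 1 (percentile 81.7) and 3 (percentile 99.7) in NT2/D1, so only the WNT list stayed above 95% of random lists. Lists were led by the genes with the highest score percentile of any single peak. Such a gene need not have a region with all 3 factors. SMAD7, BMP7, BMP4 and LEFTY1 led the first list. SMAD7, an inhibitor of this signalling, had a fold of 21.7 for OCT4 in NT2/D1 and 12.7 in H9. It had a region with all 3 factors in H9 only. Folds are not on the same scale in the lines, since the median OCT4 fold was 8.71 in NT2/D1 and 4.52 in H9. SPRED2, DUSP6, SPRY2 and ETV1 led the FGF and ERK list. DUSP6, an ERK phosphatase gene, had folds of 18.0, 11.2 and 33.0 for SOX2, OCT4 and NANOG in H9 and 13.3, 14.4 and 12.3 in NT2/D1. WNT3, SFRP2, FZD7 and WNT5B led the WNT list, and SFRP2, a secreted WNT antagonist gene, had folds of 22.5, 13.1 and 32.6 in H9 and 31.2, 11.99 and 26.4 in NT2/D1.

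Regions with all 3 factors lay near 23 of 32 neuroectoderm genes in H9 (random mean 6.52, percentile 100) and 6 in NT2/D1 (1.93, percentile 99.3). For trophectoderm the counts were 10 of 16 (3.07, percentile 100) and 3 (0.962, percentile 96.1), for mesendoderm 8 of 21 (4.31, percentile 97.0) and 3 (1.32, percentile 90.8), and for chromatin regulators 11 of 28 (5.44, percentile 99.4) and 5 (1.68, percentile 98.7). The mesendoderm list did not pass 95% of random lists in NT2/D1, nor, within 5 kb, did the trophectoderm list, with 1 gene (percentile 87.3). OTX2, ZFHX3, SOX21 and ISL1 led the neuroectoderm list, CDX2, EOMES, TFAP2A and TFAP2C the trophectoderm list, EOMES, KDR, CER1 and MESP2 the mesendoderm list, and DNMT3B, REST, JARID2 and PHC1 the chromatin list. These ranks use the highest score percentile of any single peak, and MESP2 had no region with all 3 factors in either line. EOMES is counted in both the trophectoderm and the mesendoderm list, and DNMT3B and JARID2 are also in the core pluripotency list. OTX2, a forebrain regulator, had SOX2 and NANOG folds of 22.6 and 33.1 in H9 and 36.1 and 37.0 in NT2/D1. The germ cell list had 4 of 19 genes with such a region in H9 (percentile 71.8) and 2 in NT2/D1 (percentile 83.6). DPPA5, TFAP2C, PIWIL1 and STK31 led it by single peaks, and PIWIL1 had no such region in either line. The cell cycle list had 3 of 19 (percentile 51.4) and 1 (percentile 56.8). CCND3, CDKN1B and CDKN1C were among its leading members, and of these only CCND3 had such a region.

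**Figure D2:**
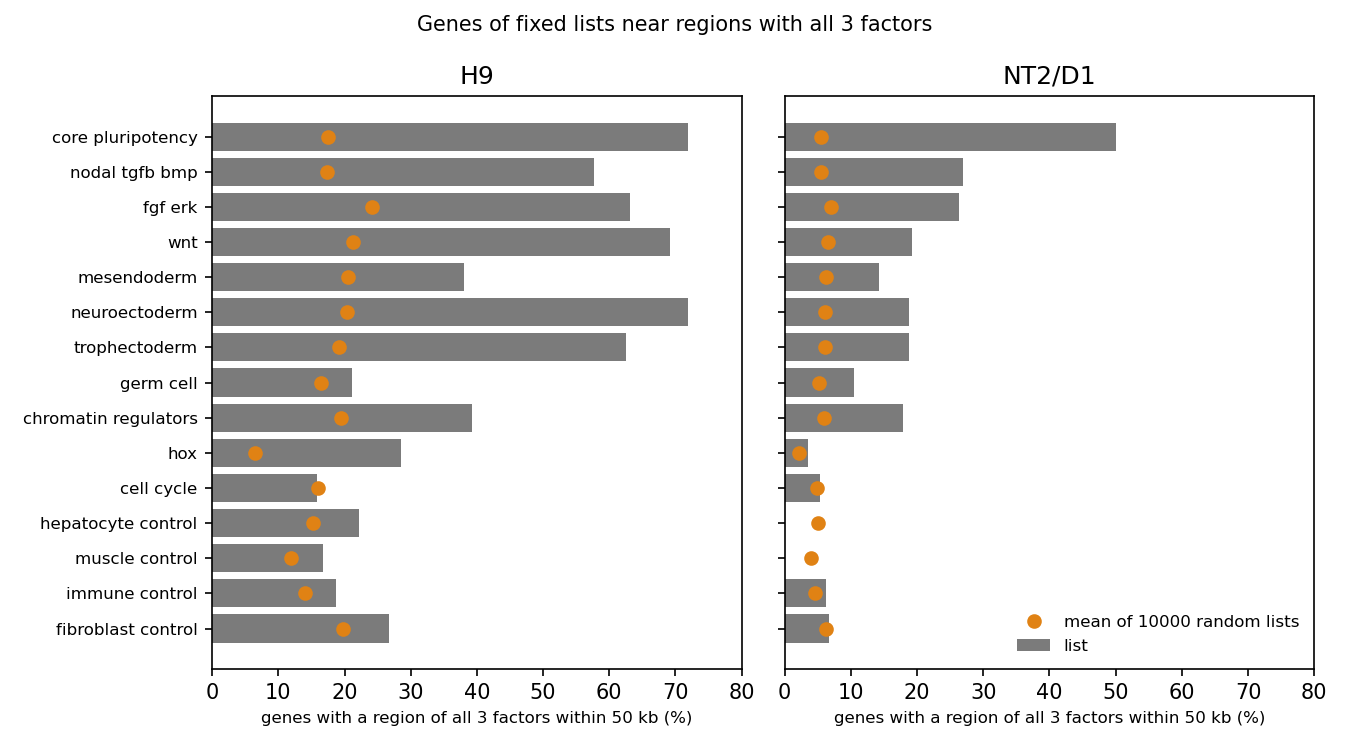
Share of the genes of each fixed list (%, horizontal axis) with a region of all 3 factors within 50 kb in H9 (left) and NT2/D1 (right). Bars are the lists and points the mean of 10000 random lists; the core pluripotency list reached 71.9% in H9 and 50% in NT2/D1.

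The HOX genes, which pattern the body axis, had peaks in H9 and no excess in NT2/D1. OCT4 peaks lay within 50 kb of 26 of 28 HOX genes in H9 (random mean 9.18, percentile 100) and of 13 in NT2/D1 (14.6, percentile 26.7). For SOX2 the counts were 14 (3.87, percentile 100) and 10 (8.85, percentile 68.7), and for NANOG 23 (7.73, percentile 100) and 6 (9.75, percentile 6.14). HOX genes lie in clusters, while the random lists drew genes singly, so these percentiles treat neighbouring genes as independent. HOXB1, HOXA13 and HOXD1 were among the leading members of the list. HOXB1, with SOX2 folds of 15.2 in H9 and 23.9 in NT2/D1, was the only HOX gene near a region with all 3 factors in NT2/D1, and 8 had one in H9. Neuroectoderm genes had OCT4 peaks in 32 of 32 cases in H9 (18.0, percentile 100) and in 26 in NT2/D1 (23.5, percentile 84.3). That NT2/D1 percentile was 98.4 with lists of equal length, 96.8 in the upper 50% by score and 99.7 within 5 kb, so the neuroectoderm contrast depends on these choices. With lists of equal length 7 HOX genes had an NT2/D1 OCT4 peak (percentile 39.7), and the difference between the lines was not tested.

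The 4 control lists stayed near the random lists for regions with all 3 factors. Their leading members were ranked by single peaks of any factor and need not have such a region. The hepatocyte list, led by APOB, AHSG, SERPINA1 and CYP2E1, had 4 of 18 genes in H9 (percentile 79.6) and 0 in NT2/D1 (percentile 19.7). The muscle list, led by MYF6, MYL2, ACTA1 and DES, had 3 of 18 (percentile 73.8) and 0 (percentile 24.5). The immune list, led by ZAP70, PTPRC, CD4 and CD8A, had 3 of 16 (percentile 71.5) and 1 (percentile 65.1). The fibroblast list, led by POSTN, COL6A1, VIM and TAGLN, had 4 of 15 (percentile 75.2) and 1 (percentile 57.1). For single factors, hepatocyte genes had fewer NT2/D1 peaks than most random lists, with percentiles of 0.735 for SOX2, 1.35 for OCT4 and 8.425 for NANOG. The single-factor percentiles of the other control lists in NT2/D1 ran from 25.5 (immune, OCT4) to 85.7 (muscle, OCT4).

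Peaks were distributed over the chromosomes differently in the lines. Chromosomes 1, 2, 3, 7, 9 and 12 held 63.0% of the NT2/D1 SOX2 peaks (95% interval 62.6 to 63.5), 61.4% of the NANOG peaks (60.9 to 61.9) and 48.5% of the OCT4 peaks (48.1 to 49.0). In H9 they held 36.8 to 38.9%. These 6 were picked without a rule after the lists had been seen, and others were also high: chromosome 21 had a higher ratio to the H9 mean than each of them in all 3 lists, and chromosomes 19 and 20 a higher one than chromosome 3 for OCT4 and NANOG. By a rule also set afterwards, the 10 chromosomes above the H9 mean in both SOX2 and NANOG (1, 2, 3, 7, 9, 12, 15, 19, 20 and 21) held 59.2% of the OCT4 peaks (58.8 to 59.7), which had no part in choosing them, against 45.7 to 46.2% in H9. The share on chromosome 1 was 2.10 times the H9 mean for SOX2, 2.09 times for NANOG and 1.41 times for OCT4. On chromosome 21 the ratios were 2.27, 2.23 and 1.54, and on chromosome 6, which holds POU5F1, 0.294, 0.294 and 0.598.

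**Figure D3:**
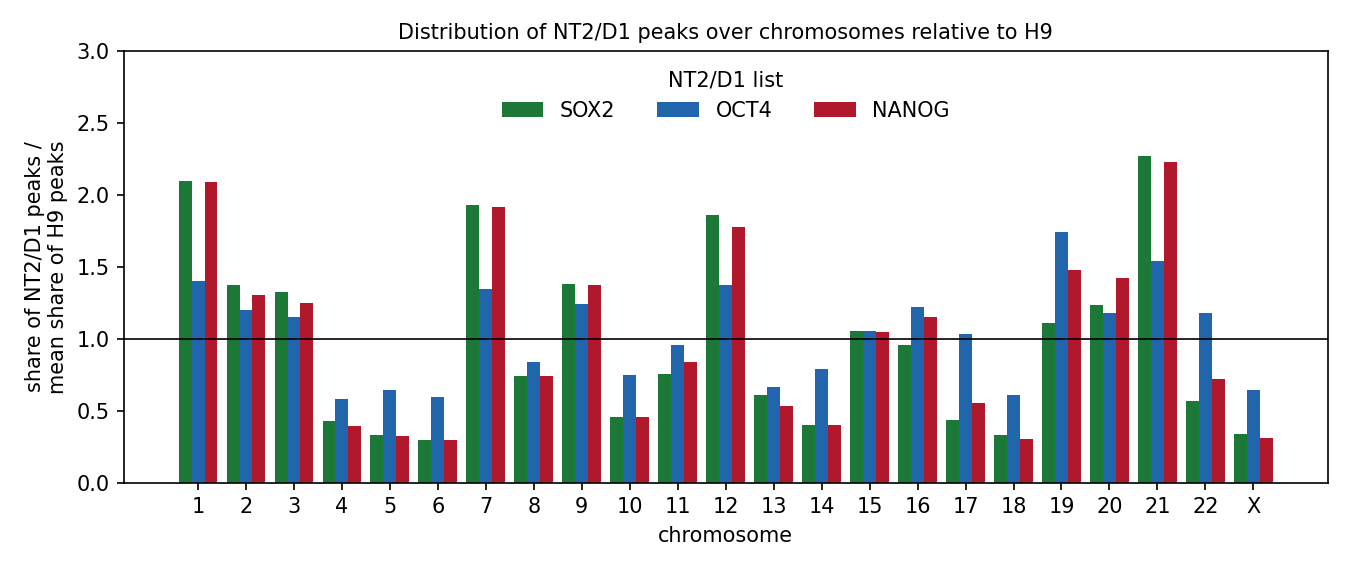
Share of NT2/D1 peaks on each chromosome divided by the mean share of the 3 H9 lists (vertical axis, ratio) for chromosomes 1 to 22 and X (horizontal axis), with a line at a ratio of 1. Bars are the NT2/D1 SOX2, OCT4 and NANOG lists; chromosomes 1, 7, 12 and 21 stand highest for SOX2 and NANOG, and 5, 6, 18 and X are among the lowest.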

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

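The tests of weak false calls and of a shared run or control on the chromosome pattern, the test of the exchanged labels, the count per HOX cluster, the draws of neighbouring peaks and the comparison of the HOX surroundings with their own chromosomes were chosen after the result was seen.

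By the titles, the number of peaks moved in opposite directions between factors in the 2 lines. The difference was not tested because each factor and line had 1 library. NANOG had 14546 more peaks than SOX2 in H9, and in NT2/D1 the difference was -4215. NANOG had 4320 more peaks than OCT4 in H9, and in NT2/D1 the difference was -11961. In NT2/D1 each direction changed under 1 of 2 stricter thresholds. Against OCT4, NANOG had more peaks at an FDR of at most 5% (26097 against 10367) and fewer at a fold of at least 10 (2420 against 15201). Against SOX2, it had fewer at that FDR (26097 against 31892) and more at that fold (2420 against 1452). The FDR limit is not alike for NANOG and OCT4, since it removes the strongest peaks of the NT2/D1 NANOG list, where FDR rose with score, and not of the OCT4 list, where it fell. With the NT2/D1 OCT4 and NANOG libraries exchanged, NANOG would have 46169 peaks, against 34208 for OCT4 and 38423 for SOX2. NANOG would then have the most peaks in both lines, so the opposite directions rest on the titles.

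NT2/D1 peaks were spread over the chromosomes differently from H9 peaks. Weak false calls are argued against as far as score marks a weak call. On the chromosomes above the H9 mean in the lower 9 deciles of a list by score, the highest decile exceeded that of every H9 list by 12.9 percentage points or more (63.2% against at most 50.2% for OCT4, the smallest gap). Of the NT2/D1 lists, only OCT4 had a lower median FDR in the highest decile (1.13%) than in the lowest (21.8%). For SOX2 and NANOG it was 12.2 and 15.1% in the highest decile and 1.25 and 1.45% in the lowest. False calls with high scores therefore stay open in the SOX2 and NANOG lists. A run or control shared by SOX2 and NANOG is argued against as the whole cause, since on the 10 chromosomes above the H9 mean in both, the OCT4 list, from another run and control, had 59.2% against at most 46.2% in H9. A candidate explanation is the DNA copy number of the line, because chromosomes with more NT2/D1 peaks of their own were also those where more of the separate H9 all-factor regions were recovered, with a lowest Spearman rho of 0.628 across 23 chromosomes. Another cause acting on whole chromosomes stays open, since copy number was not measured here, and the size of the effect in SOX2 and NANOG may still include their shared control.

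The OCT4 and NANOG labels of the NT2/D1 libraries contradict each other between title and source name. The values went against an exchange but do not settle it. The library titled OCT4 favoured H9 regions with OCT4 and no NANOG over those with NANOG and no OCT4 by a ratio of 1.14, and the library titled NANOG by 0.462. The first ratio was 2.46 times the second, with a resampled interval of 2.21 to 2.74, where an exchange would put it below 1. Depth and control also differ between these libraries. The NT2/D1 SOX2 list, which shared a control with the library titled NANOG, also overlapped a larger share of H9 NANOG peaks (11.6%) than of H9 OCT4 peaks (10.6%). The lean toward H9 NANOG is thus not particular to the library titled NANOG. A difference between the controls cannot be told from one between the factors here, and a labelling error of another kind stays open.

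HOX genes had OCT4 peaks in H9 and no excess in NT2/D1, and neuroectoderm genes showed a like but setting-dependent contrast. Lower sensitivity of the NT2/D1 list for weak sites or promoters is argued against as the whole cause at neuroectoderm genes, where the share of H9 OCT4 peaks recovered (32 of 204, 15.7% against 27.8% for peaks matched on score and promoter position) lay at percentile 0 of 10000 matched draws, below every draw, and also at percentile 0 of draws of runs of neighbouring peaks. At HOX genes it stays open: the share (10 of 84, 11.9% against 22.9%) lay at percentile 0.36 when peaks were drawn singly and at percentile 1 when drawn in runs, and the cluster on chromosome 2 went the other way, with 26.1% recovered against 19.0%. A loss of DNA at HOX loci stays open too, since surrounding NT2/D1 peaks stood at 0.962 times the genome-wide ratio (interval 0.799 to 1.16) but at 0.715 times that of their own chromosomes (0.594 to 0.861), with 0.568 on chromosome 17, 0.583 on 12, 0.765 on 2 and 1.01 on 7. These intervals count peaks of the 3 factors as independent, though they often share a site, so they are likely too narrow. A difference in OCT4 binding between the lines may remain as a hypothesis for these genes, and the calling settings that differ between the lines were not separated from it. The draws were also not matched on chromosome or on the other factors. The NT2/D1 OCT4 list recovered 53.0% of H9 regions with all 3 factors but 10.9% of those with OCT4 alone. Sensitivity that varies with these was therefore not tested.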

How the results depend on the processing

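The runs without chromosomes 1, 2, 3, 7, 9 and 12, picked without a rule, and the gene lists with exchanged libraries were chosen after seeing the data. Of 93 alternatives run on the results of the comparisons, 42 stayed within counting error or 1.5 times, and 51 moved. No paired analysis was possible because each group, a factor in a line, had 1 library. Motif alternatives were not run, and local placement gave no fold for the regions with all 3 factors in both lines, as no placement held such a region. The depth of NT2/D1 limits what a missing peak shows there.

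The share of H9 peaks called in NT2/D1 was highest for OCT4 under every alternative run on it except the exchange. The FDR and fold limits were not run on this share. For SOX2, OCT4 and NANOG it was 21.9, 33.7 and 12.7% in the upper 50% by score, 13.1, 27.2 and 12.001% with equal lengths, 14.7, 23.4 and 8.11% with summits within 200 bp, 10.5, 17.0 and 3.42% with a reciprocal overlap of 50%, and 13.7, 23.1 and 7.80% without the 6 chromosomes. Without the widest 1% of peaks and without chromosomes other than 1 to 22 and X it was 25.1% for OCT4 and 9.36% for NANOG. With the libraries exchanged it was 8.33% for OCT4 and 23.8% for NANOG, since each list took the other's place. Regions with all 3 factors in H9 numbered 5055 in the upper 50%, which holds fewer peaks. Without the 6 chromosomes there were 5034 in H9, 864 in NT2/D1 and 629 in both lines. Against local placement the folds were 392 for all 3 factors in H9, 63.2 in NT2/D1, and 9.61, 16.3 and 6.13 for SOX2, OCT4 and NANOG shared between lines.

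Peaks at an FDR of at most 5% numbered 8941 for H9 SOX2, 11541 for H9 OCT4 and 10367 for NT2/D1 OCT4. At a fold of at least 10 there were 2354, 815 and 4880 SOX2, OCT4 and NANOG peaks in H9 and 1452, 15201 and 2420 in NT2/D1, so the order of the factors changed; the cause was not tested. Within 5 kb of a TSS lay 10.3, 19.4 and 14.6% of H9 peaks and 10.4, 18.4 and 12.4% of NT2/D1 peaks. With equal lengths the share within 1 kb was 6.05% for H9 NANOG and 3.68, 14.8 and 4.75% for NT2/D1.

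Within 5 kb, 7 core pluripotency genes had a region with all 3 factors in NT2/D1, and 4 lists other than controls passed 95% of random lists there (core pluripotency, WNT, neuroectoderm and chromatin). HOX genes with an NT2/D1 OCT4 peak numbered 7 with equal lengths and 6 with the libraries exchanged. Of 370 alternatives on other list counts, 151 moved by over 1.5 times, and of 201 on the number of lists with a peak at named regions and core genes, 20 did. Of 42 on other shares, 38 left their interval.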

Other observations

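The summit distances, the comparison of the highest peaks and the count of peaks on unplaced sequence were chosen after seeing the data. Where the 3 factors met, their summits lay close together. These regions were chosen because their peaks overlap, which limits the distances, and no random distance was set beside them. In regions with all 3 factors, the median distance between the strongest SOX2 and NANOG summits was 23 bp in H9 and 32 bp in NT2/D1. For SOX2 and OCT4 it was 30 and 32 bp, and for OCT4 and NANOG 33 and 35 bp. Summits of SOX2 and NANOG lay within 50 bp of each other in 76.1% of these regions in H9 and 62.9% in NT2/D1.

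Among the 2000 peaks with the highest score in each list, every NT2/D1 list overlapped the H9 list of its own factor most. The shares were 32.4% for SOX2 (95% interval 30.4 to 34.5), 41.8% for OCT4 (39.6 to 43.9) and 33.3% for NANOG (31.3 to 35.4). The NT2/D1 SOX2 list overlapped the H9 NANOG list at 31.6% (29.6 to 33.6), within the interval of its own factor. These shares were not set beside random placements. Over all peaks, each NT2/D1 list had its highest share with H9 NANOG, the H9 list with the most peaks and the highest median width (10.6% for SOX2, 18.2% for OCT4 and 10.1% for NANOG). Relative to uniform random placement the order was another. The fold for NT2/D1 SOX2 was highest with H9 SOX2 (10.98, against 9.09 with OCT4 and 7.54 with NANOG), while that for NT2/D1 NANOG was lowest with H9 NANOG (7.60, against 10.1 with SOX2 and 8.74 with OCT4). For NT2/D1 OCT4 it was 21.4 with H9 OCT4, 20.7 with SOX2 and 14.3 with NANOG, and under local placement it was higher with H9 SOX2 (17.7) than with H9 OCT4 (16.6). Which H9 list an NT2/D1 list overlapped most therefore depended on the measure. At the level of genes, 538 genes had a region with all 3 factors within 50 kb in both lines. Independent lists of 2730 and 867 genes out of 18204 would share 130. For single factors the excess was smaller in proportion. Genes with a peak in both lines numbered 3176 against 2580 for SOX2, 6731 against 5888 for OCT4 and 4715 against 4159 for NANOG. Unlike the random gene lists, these independent counts were not matched on the span in which a peak would be assigned to a gene. How much of the excess rests on span was not tested.

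Peaks on mitochondrial DNA or on unplaced sequence numbered 14, 40 and 15 in the NT2/D1 SOX2, OCT4 and NANOG lists and 0 in the H9 lists. The NT2/D1 OCT4 peak on mitochondrial DNA held 948 tags, the most of any peak in that list.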
